A study of Mus musculus with 12 samples.

How the data were processed

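RNA of the ascending aorta of mice was labelled with biotin and hybridised to a 1-colour Affymetrix whole-transcript array by the authors, with 12 arrays in 4 groups of 3. Per the submitters' processing notes the signals were normalised with RMA in Partek 6.4. The deposited values of 35556 probe sets are linear RMA intensity, not log2 values, with medians per array between 301 and 334 and maxima between 30090 and 32420, and log2 was taken first. No 2 arrays held identical values, and there were no columns of other samples. Raw scans, values per probe and detection calls were not used, so precision rests on the number of arrays.

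The annotation named 23410 probe sets. A gene was represented by its probe set of highest mean among the 21789 probe sets with 1 symbol, which gave 19938 genes, and 21698 of those probe sets were matched to reference symbols by Entrez ID with 0 symbols updated. The 1621 probe sets with several symbols and the 12146 with none were left out of the gene tests, which also leaves out Fbn1. Genes whose mean lay under the 25th percentile of the annotated probe sets (log2 7.31, an intensity of 159) were not tested, which left 14944 genes, 918 of them with several probe sets.

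One coefficient per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with 8 residual degrees of freedom, 4.54 added by the prior. Contrasts were knockout against control in each Fbn1 genotype and as the mean of both, Fbn1 mutant against wild-type among controls and among knockouts, and the difference of the knockout effects. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Of all 14944 genes tested, called or not, the groups did not overlap in 5349 (35.8%) for knockout against control in the wild-type and in 5358 (35.9%) in the mutant, where chance gives 10% with 3 arrays against 3. For the Fbn1 mutant against wild-type they did not overlap in 4195 (28.1%) among controls and in 3926 (26.3%) among knockouts. The Tgfbr2 level was also compared by an exact permutation test over all 20 assignments.

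There were 24 gene lists. They held TGF-beta pathway members, SMAD-induced TGF-beta targets, smooth muscle contractile, elastic fibre, collagen, proteoglycan, protease and cell division genes, markers of macrophages, lymphocytes, endothelium, fibroblasts, adipocytes, cardiac muscle, skeletal muscle, nerve and erythroid cells, and cytokine and chemokine, interferon-induced, immediate early, ERK feedback, cartilage and bone, vasoactive and endoplasmic reticulum stress genes. Of their 666 entries 549 were tested, from 526 different genes. Each list was tested with limma's camera at its preset correlation of 0.01, adjusted over the 24 lists, and again with a correlation estimated from the residuals. Fry gave tests that do not compare a list with other genes, and members were also adjusted over the list alone. The groups, contrasts, tests, lists, rule for named genes and 12 kinds of alternative were fixed before the data were examined.

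Genes named in each comparison are the 10 largest increases and the 10 largest decreases past the threshold whose groups do not overlap (in both genotypes for the mean, and without that condition for the difference), leaving out predicted genes, receptors of smell and symbols beginning with Mir or Snor, other small RNAs being kept. Tgfbr2 is given in every comparison, and up to 4 members of smallest p may be named per list. Any other gene named was chosen after its values were seen, and so were the lists of clock and heat shock genes.

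The procedure was tested on simulated data with the spread of these arrays, 14944 genes and 200 changed ones. At a log2 change of 0.5 it called 86%, 84%, 96%, 86%, 81% and 62% of changed genes in the 6 contrasts in the order given, and at least 97% at a log2 change of 1. Of the calls 2.62%, 6.22%, 2.97%, 6.57%, 3.74% and 3.57% were false, which is above the 5% aimed at for the knockout in the mutant and for the mutation among controls. Camera called 4 of 4 lists shifted by 0.3 in each contrast and 1 unshifted list in the difference of effects. Simulated genes were independent, which the genes of a real list are not.

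Alternatives covered the filter on dim probe sets, the scaling between arrays, the handling of probe sets, the variance model, array weights, the arrays in the fit, the number in the titles as a block, the correlation of camera and leaving out each array. Of these, 3 were added after the data were seen: leaving out the 2 arrays of highest Ucp1, and the adipocyte or the immediate early list score as a covariate. For each comparison of 3 arrays against 3 the fit was made for all 10 splits of the 6 arrays, the real one and 9 others. For the mean effect it was made for the real labels and 99 drawn shufflings of the knockout labels, and for the difference for the real data and 99 shufflings of the residuals of a fit without it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.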

Results

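Gene expression was measured on 12 whole-transcript microarrays of the ascending aorta of mice aged 6 weeks, in 4 groups of 3 arrays each. The groups crossed the Fbn1 genotype, wild-type or heterozygous for the C1039G allele used as a mouse model of Marfan syndrome, with the state of Tgfbr2 in smooth muscle cells. Every group carried floxed Tgfbr2, the gene of the type II TGF-beta receptor, and a Cre that acts in smooth muscle cells once tamoxifen is given. Knockout groups received 1 mg of tamoxifen on 5 days from an age of 4 weeks and control groups received corn oil, so that each comparison of knockout with control is also one of tamoxifen with its vehicle. The labels do not say whether the 3 arrays of a group came from 3 animals, and the p-values measure the spread between these samples. Median intensity per array lay between 301 and 334, correlations of log2 values lay between 0.995 and 0.997 within groups and between 0.991 and 0.996 across groups, and the number of arrays limits the precision. The first principal component held 39.7% of the variance and set the 6 knockout arrays apart from the 6 control arrays, while the second held 19.8% and set the Fbn1 mutant arrays apart from the wild-type arrays. Changes below are log2 differences of group means with limma's standard error, each from 3 arrays per group, and an array is named by its group and the number in its title.

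Tgfbr2 itself was read by 1 probe set, which did not measure a clear loss. Its log2 level was 11.95 ± 0.01 (SD, n = 3) in Fbn1 wild-type controls and 11.87 ± 0.08 in wild-type knockouts, a difference of -0.08 with an exact two-sided permutation p of 0.2. In the Fbn1 mutant the level was 11.99 ± 0.04 (SD, n = 3) in controls and 12.03 ± 0.05 in knockouts, a difference of 0.04 with an exact two-sided permutation p of 0.3. The smallest p that 3 arrays against 3 allow is 0.1, and limma's adjusted p was 0.324 and 0.594. Where its probes lie was not analysed here, and "knockout" is used as the name the labels give. Pmepa1, which restrains SMAD signalling, fell by 0.40 ± 0.05 in the wild-type and by 0.55 ± 0.05 in the mutant, and Ldlrad4, a related inhibitor, fell by 0.58 ± 0.07 and by 0.67 ± 0.07. The Fbn1 transcript had no probe set annotated to that gene alone and was not analysed here.

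The first comparison set arrays labelled knockout against controls in the aorta with normal Fbn1. Of the gene lists 12 passed upward and 0 downward, 1 of them also with an estimated correlation. Ddah1, which degrades an endogenous inhibitor of nitric oxide synthesis, rose by 2.20 ± 0.25, a 4.59-fold increase, and Thbs1, the matricellular protein thrombospondin 1, rose by 1.86 ± 0.24. The monocyte chemokine Ccl8 rose by 1.87 ± 0.15, and the macrophage receptors Fcrls and Vsig4 rose by 1.83 ± 0.10 and 1.78 ± 0.28. Ccna2, the cyclin of S phase, rose by 1.81 ± 0.18. Cthrc1, a secreted protein of activated fibroblasts, rose by 1.81 ± 0.11, the collagen prolyl hydroxylase subunit P4ha3 by 1.68 ± 0.21, the protease inhibitor Serpina3n by 1.71 ± 0.13 and D17H6S56E-5 by 1.83 ± 0.12. Among the largest decreases, Acan, the proteoglycan aggrecan, fell by 1.34 ± 0.19 and Mylk4, a myosin light chain kinase, fell by 1.31 ± 0.08. Sphkap, which binds sphingosine kinase and anchors protein kinase A, fell by 1.32 ± 0.31 and the peptide transporter gene Slc15a2 by 1.19 ± 0.33. The growth factor gene Bmp3 fell by 1.12 ± 0.14 and the synaptotagmin Syt15 by 1.00 ± 0.15. Pnldc1, an RNA exonuclease, fell by 1.16 ± 0.08, Smim5 by 1.12 ± 0.12, the orphan receptor Gpr165 by 1.08 ± 0.15 and Gmnc, a regulator of multiciliated cells, by 1.06 ± 0.16. In all 20 of these genes each knockout array lay beyond each control array, as the rule for naming them requires, and limma's adjusted p was at most 0.0241. In all, 2814 of 14944 genes changed, 1370 upward and 1444 downward, and of these 90 rose and 11 fell at least 2-fold. The count was 1874 without wild-type knockout 1 and 1836 without wild-type knockout 3. Neither direction prevailed throughout, as upward genes outnumbered downward ones with quantile normalization (1514 and 1475) and without wild-type knockout 1 (1076 and 798). Slc15a2 was no longer called without wild-type control 2, wild-type knockout 2 or wild-type knockout 3, with an adjusted p of up to 0.0961.

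Among the gene lists, the macrophage and cell division lists moved furthest in the wild-type. Of 27 measured macrophage genes 26 rose and 0 fell (27 rose adjusted over the list alone), with a median of 1.00 and a camera adjusted p of 6.14e-29, against adjusted p = 0.0651 with an estimated correlation. The Fc receptor genes Fcgr2b and Fcgr3 rose by 1.16 ± 0.06 and 1.06 ± 0.07, the integrin Itgam by 1.03 ± 0.06 and the macrophage marker Adgre1 by 1.22 ± 0.08. Of 29 cell division genes 27 rose (28 adjusted over the list alone), with a median of 0.81 and a camera adjusted p of 9.49e-25, against adjusted p = 0.0778 with an estimated correlation. Examples were the cyclin Ccnb2 at 1.59 ± 0.14 and the mitotic kinases Aurkb and Plk1 at 1.05 ± 0.11 and 1.02 ± 0.11. The list of cytokines and chemokines was the only one of the 12 calls to hold with an estimated correlation, at adjusted p = 0.0489 with an estimated correlation. Its median was 0.34, and 11 of 26 members rose (13 adjusted over the list alone), among them the chemokines Ccl2 at 0.98 ± 0.08, Ccl9 at 1.10 ± 0.13 and Ccl7 at 0.93 ± 0.12. Interferon-induced genes had a median of 0.34 with 6 of 23 risen (7 adjusted over the list alone), and endothelial genes a median of 0.28 with 8 of 24 risen and 1 fallen (13 and 1 adjusted over the list alone). Both passed with a camera adjusted p of 1.06e-05, against adjusted p = 0.43 and 0.417 with an estimated correlation. Nos3, the endothelial nitric oxide synthase, rose by 0.54 ± 0.09 and the interferon-induced proteasome subunit Psmb9 by 0.36 ± 0.05. Matrix proteases and their inhibitors had a median of 0.11 and a camera adjusted p of 0.00721, against adjusted p = 0.0711 with an estimated correlation, with 5 of 28 risen and 2 fallen (8 and 2 adjusted over the list alone). The cathepsins Ctss and Ctsk rose by 1.35 ± 0.09 and 0.62 ± 0.05, and Timp1, an inhibitor of metalloproteinases, rose by 1.54 ± 0.13.

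Collagen, fibroblast, cardiac, nerve, immediate early and ERK feedback lists also passed upward in the wild-type, each by small medians. Collagens had a median of 0.08 with 8 of 29 risen and 4 fallen (10 and 6 adjusted over the list alone), and Col12a1, a fibril-associated collagen, rose by 1.21 ± 0.12 while the basement membrane collagen Col15a1 fell by 0.60 ± 0.07. Fibroblast genes had a median of 0.10 with 7 of 24 risen and 1 fallen (9 and 2 adjusted over the list alone), and the proteoglycan lumican, Lum, rose by 0.51 ± 0.08. Cardiac genes had a median of 0.13 with 3 of 24 risen and 1 fallen (3 and 1 adjusted over the list alone). Nerve genes had a median of 0.12 with 3 of 13 risen and 1 fallen (4 and 1 adjusted over the list alone). Immediate early genes had a median of 0.24 with 3 of 30 risen (3 adjusted over the list alone), including Myc at 0.97 ± 0.16, and ERK feedback genes a median of 0.12 with 5 of 20 risen and 1 fallen (5 and 2 adjusted over the list alone), including the cyclin Ccnd1 at 0.67 ± 0.12. Camera's adjusted p was 0.0421, 0.0137, 0.00721, 0.0421, 0.00132 and 0.0224 in the order of these lists, and each had adjusted p = 0.43 with an estimated correlation. The cardiac call ended without wild-type knockout 1 (adjusted p 0.0648) and the fibroblast call without wild-type control 2 (0.084), while the collagen, nerve and ERK feedback calls ended without wild-type control 1 (0.14, 0.124 and 0.0598). Collagen also lost its call without wild-type control 2, wild-type knockout 3, mutant control 1 or mutant control 3 (0.0526, 0.0771, 0.0502 and 0.0503) and nerve without wild-type knockout 2, mutant control 2 or mutant knockout 2 (0.11, 0.0552 and 0.0503), and other splits of the 6 arrays gave up to 14 lists. The collagen median was 0.05 without wild-type control 1 and 0.04 without wild-type control 2. The collagen call ended as well with quantile normalization (0.0582), with each array centred on its median (0.0514) and with the number in the titles as a block (0.0579). The nerve call did with quantile normalization (0.066), array weights (0.0598), only the groups of the comparison in the fit (0.0536) and the adipocyte score as a covariate (0.0516), and the ERK feedback call with the filter at the median (0.0983). With the immediate early score, which like the adipocyte score was chosen after the data were seen, the nerve (0.134), ERK feedback (0.448) and immediate early (0.811) calls ended. Over all alternatives the adjusted p lay between 0.00467 and 0.43 for collagen, 0.0117 and 0.43 for nerve, 0.00715 and 0.448 for ERK feedback and 2.88e-05 and 0.811 for immediate early genes.

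The lists closest to the target and to the muscle itself passed in neither direction in the wild-type. SMAD-induced TGF-beta targets had a median of 0.15 with 7 of 28 risen and 4 fallen (11 and 4 adjusted over the list alone), and Nox4, an NADPH oxidase, fell by 0.87 ± 0.09 while the collagen-binding integrin Itga11 rose by 0.75 ± 0.08. Smooth muscle contractile genes had a median of -0.06 with 2 of 29 risen and 8 fallen (3 and 8 adjusted over the list alone), among them Npnt, a matrix ligand of integrins, which fell by 0.39 ± 0.05. The TGF-beta pathway list had a median of 0.02 and a mean of -0.02 and tested downward, with 3 of 24 risen and 8 fallen (5 and 9 adjusted over the list alone), and the latent TGF-beta binding proteins Ltbp1 and Ltbp3 fell by 0.37 ± 0.07 and 0.32 ± 0.05. Camera's adjusted p was 0.0802 for the target and the contractile lists and 0.5 for the pathway list. Elastic fibre genes had 5 of 18 risen and 5 fallen (5 and 6 adjusted over the list alone; adjusted p 0.5), and the proteoglycan list 7 of 27 risen and 4 fallen (11 and 5 adjusted over the list alone; adjusted p 0.114). The skeletal muscle list had a median of 0.02 and a mean of -0.04 and tested downward (adjusted p 0.901). Of the rest, adjusted p was 0.264 for lymphocyte, 0.173 for adipocyte, 0.204 for erythroid, 0.0645 for cartilage and bone, 0.0757 for vasoactive and 0.444 for endoplasmic reticulum stress genes.

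**Figure D1:**
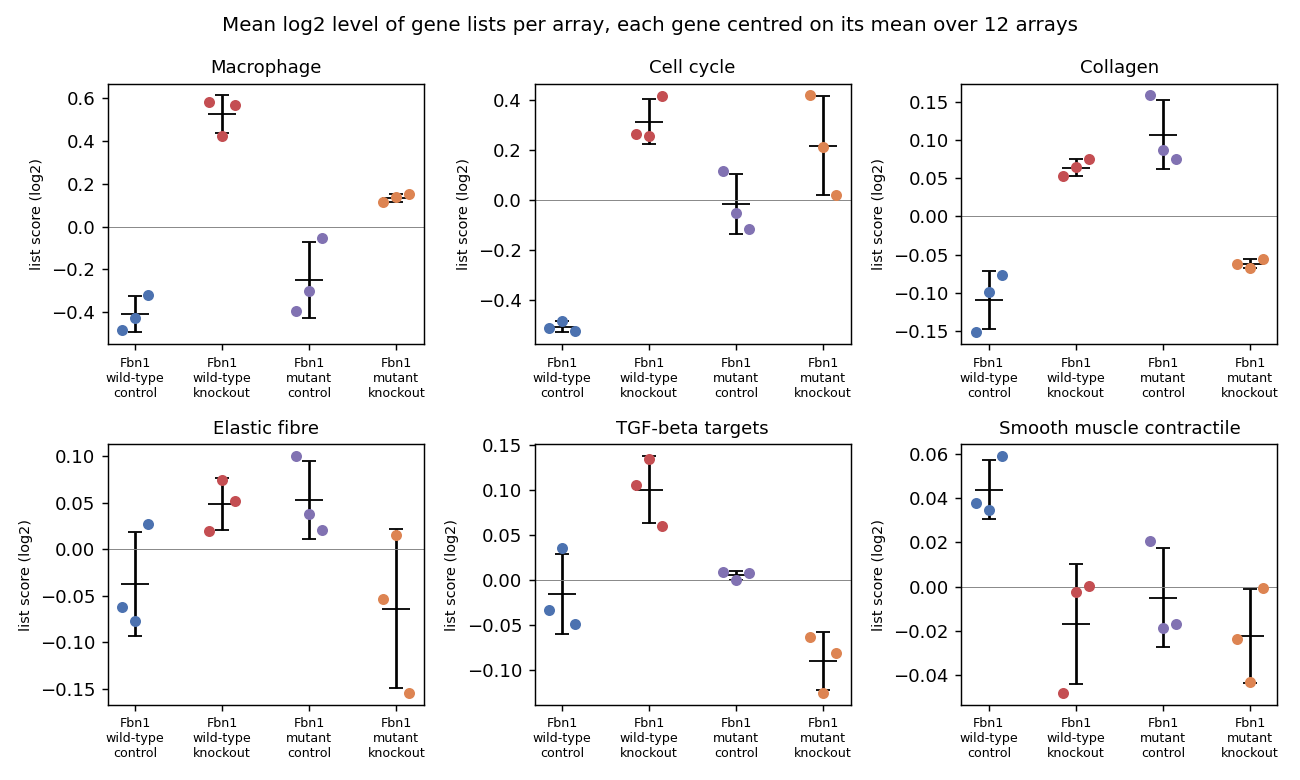
Scores of gene lists on each of the 12 arrays, as the mean log2 value of a list's tested genes relative to the mean of all arrays (vertical axis), by group (horizontal axis). Points are arrays, horizontal lines group means of 3 arrays and bars 1 SD. Macrophage scores differ between knockout and control arrays by 0.94 in the Fbn1 wild-type and by 0.39 in the Fbn1 mutant.

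The same comparison was made in the Fbn1 mutant, the Marfan model. Atf3, a stress-induced transcription factor, rose by 2.15 ± 0.54, and Nr4a1, an immediate early nuclear receptor, rose by 1.89 ± 0.41. Vsig4 rose by 1.79 ± 0.28, Thbs1 by 1.50 ± 0.24 and Ddah1 by 1.29 ± 0.25. Adamtsl2, a protein that binds microfibrils, rose by 1.19 ± 0.09, Timp4, an inhibitor of metalloproteinases, by 1.25 ± 0.15, and the potassium channel Kcnk3 by 1.24 ± 0.11. The small GTPase Rasl10b rose by 1.30 ± 0.13 and the atrial myosin light chain Myl7 by 1.21 ± 0.27. Sphkap fell by 2.42 ± 0.31, Mylk4 by 1.52 ± 0.08 and Nox4 by 1.46 ± 0.09. Col15a1 fell by 1.39 ± 0.07, Lratd1 by 1.43 ± 0.07 and the serotonin receptor gene Htr1b by 1.22 ± 0.15. Igfbp2, which binds insulin-like growth factors, fell by 1.07 ± 0.14, the receptor phosphatase Ptprz1 by 1.04 ± 0.15, Gmnc by 1.10 ± 0.16 and Ppp1r36 by 1.07 ± 0.09. In these 20 genes each knockout array lay beyond each control array, as the naming rule requires, and limma's adjusted p was at most 0.0219. In all, 2008 genes changed, 1145 upward and 863 downward, and of these 18 rose and 20 fell at least 2-fold. The upward excess was absent or turned with the filter at the median (696 up and 870 down) and with quantile normalization (924 and 925). The same held without mutant control 2 (448 and 448) and without mutant knockout 3 (747 and 971). With the immediate early score as a covariate, chosen after the data were seen, 154 rose and 244 fell.

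The immediate early list score differed between arrays of 1 group, at 0.61, -0.05 and 0.35 in mutant knockouts 1 to 3 against -0.34, -0.28 and -0.09 in mutant controls 1 to 3. With that score as a covariate, chosen after the data were seen, 398 genes changed, and Atf3, Nr4a1, Vsig4, Thbs1, Ddah1 and Myl7 were no longer called, with adjusted p-values of up to 0.461 over all alternatives for Atf3. Ucp1, a brown fat gene chosen after its values were seen, was highest in mutant control 3 (8.58) and mutant knockout 1 (8.21), and without both arrays 1082 genes changed and Atf3, Nr4a1 and Myl7 were no longer called. The count was 1209 without mutant control 1, 896 without mutant control 2, 1160 without mutant knockout 1 and 1049 without mutant knockout 2. Atf3 also lost its call without mutant control 1, mutant control 2, mutant knockout 1 or mutant knockout 3, with an adjusted p of up to 0.0746.

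In the mutant 6 lists passed downward and 9 upward, and 0 of these 15 passed with an estimated correlation. Of 29 collagen genes 12 fell and 2 rose (17 and 3 adjusted over the list alone), with a median of -0.20 and a camera adjusted p of 3.73e-06. Besides Col15a1, the basement membrane collagens Col4a5, Col4a2 and Col4a1 fell by 0.92 ± 0.05, 0.65 ± 0.08 and 0.56 ± 0.07. Of 18 elastic fibre genes 8 fell and 1 rose (9 and 2 adjusted over the list alone), with a median of -0.12 and an adjusted p of 0.00157, and Eln, which encodes elastin, fell by 0.49 ± 0.10. Of 28 TGF-beta targets 10 fell and 2 rose (11 and 3 adjusted over the list alone), with a median of -0.04 and an adjusted p of 0.00752. Proteoglycans had a median of -0.08 with 6 of 27 fallen and 3 risen (8 and 3 adjusted over the list alone; adjusted p 0.0271), and Tnc, the matricellular protein tenascin C, fell by 0.65 ± 0.13. The TGF-beta pathway list had a median of -0.05 with 4 of 24 fallen and 2 risen (4 and 3 adjusted over the list alone), Ltbp3 among them at -0.58 ± 0.05. The endoplasmic reticulum stress list had a median of -0.05 with 2 of 25 fallen and 1 risen (2 and 1 adjusted over the list alone), and both of these lists had an adjusted p of 0.0451. In the order of these 6 lists, the values were adjusted p = 0.305, 0.336, 0.305, 0.335, 0.305 and 0.373 with an estimated correlation.

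Macrophage genes had a median of 0.35 in the mutant with 14 of 27 risen (21 adjusted over the list alone; camera adjusted p 1.47e-08), Itgam at 0.47 ± 0.06 and the complement gene C1qa at 0.51 ± 0.10. Immediate early genes had a median of 0.34 with 9 of 30 risen (10 adjusted over the list alone; adjusted p 6.99e-06), the nuclear receptor Nr4a3 at 1.02 ± 0.16 among them. Cell division genes had a median of 0.23 with 6 of 29 risen (8 adjusted over the list alone; adjusted p 0.000129), including the replication factor Mcm5 at 0.50 ± 0.06. Endothelial genes had a median of 0.31 with 7 of 24 risen and 1 fallen (13 and 1 adjusted over the list alone; adjusted p 0.000217), and Plvap, a protein of endothelial diaphragms, rose by 0.62 ± 0.09. In the order of these 4 lists, the values were adjusted p = 0.305, 0.373, 0.434 and 0.373 with an estimated correlation. Interferon-induced genes had a median of 0.28 with 3 of 23 risen (3 adjusted over the list alone; adjusted p 0.000524) and cardiac genes a median of 0.23 with 6 of 24 risen and 1 fallen (6 and 1 adjusted over the list alone; adjusted p 0.000524), the troponin Tnnt2 at 1.01 ± 0.16. Cytokines and chemokines had a median of 0.19 with 3 of 26 risen (3 adjusted over the list alone; adjusted p 0.00594), skeletal muscle genes a median of 0.12 with 6 of 15 risen and 1 fallen (9 and 1 adjusted over the list alone; adjusted p 0.0127), and ERK feedback genes a median of 0.19 with 5 of 20 risen (10 risen and 1 fallen adjusted over the list alone; adjusted p 0.0185). In the order of these 5 lists, the values were adjusted p = 0.462, 0.308, 0.305, 0.305 and 0.462 with an estimated correlation. The protease, fibroblast and erythroid lists passed in neither direction and had a median and a mean of opposite sign.

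Leaving out 1 array ended several of these calls in the mutant. Without mutant knockout 3 the elastic fibre (adjusted p 0.0553), proteoglycan (0.0665), TGF-beta pathway (0.17) and endoplasmic reticulum stress (0.384) lists no longer passed, and without mutant knockout 2 the interferon (0.0559) and TGF-beta pathway (0.0587) lists did not. The proteoglycan list also lost its call without mutant control 3 (0.24), the ERK feedback list without mutant knockout 1 (0.155), and the endoplasmic reticulum stress list without mutant control 1 (0.0776) or wild-type control 3 (0.0528), and other splits of the 6 arrays gave up to 15 lists. Without the 2 arrays of highest Ucp1 the cell division list had a median of 0.07 and the proteoglycan list one of -0.0016, and neither passed (adjusted p 0.205 and 0.324, over all alternatives 1.11e-09 to 0.434 and 0.00362 to 0.335). The TGF-beta pathway call also ended with the filter at the median (0.249), with quantile normalization (0.129), with each array centred on its median (0.0507), with the mean of the probe sets (0.0563), with array weights (0.117) and with only the groups of the comparison in the fit (0.0517), its adjusted p lying between 0.00827 and 0.305 over all alternatives. The endoplasmic reticulum stress call ended with that filter (0.188), both scalings (0.103 and 0.0682) and array weights (0.153), its adjusted p lying between 0.0045 and 0.919. The filter at the median ended the proteoglycan and the skeletal muscle calls too (0.129 each, the latter between 0.00329 and 0.305 over all alternatives), and array weights the proteoglycan call (0.0584). The ERK feedback call ended without the 2 arrays of highest Ucp1 (0.0721) and with the adipocyte score (0.0589), the endoplasmic reticulum stress call with the adipocyte score (0.0657). With the immediate early score the elastic fibre and proteoglycan (0.131 each), cytokine (0.197), ERK feedback and immediate early (0.715 each) and endoplasmic reticulum stress (0.919) calls ended. Over all alternatives the adjusted p lay between 5.6e-05 and 0.336 for elastic fibre, 0.0019 and 0.305 for cytokine, 0.000394 and 0.715 for ERK feedback and 5.08e-11 and 0.715 for immediate early genes.

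Averaged over both Fbn1 genotypes, the knockout changed 4316 genes, 2244 upward and 2072 downward, and of these 24 rose and 9 fell at least 2-fold. Downward genes were the more numerous with the filter at the median (1337 up and 1926 down) and with array weights (2618 and 2873). So they were without wild-type knockout 2 (1917 and 2036) and without mutant knockout 3 (1972 and 2358). Vsig4 rose by 1.78 ± 0.20, Ddah1 by 1.75 ± 0.17 and Thbs1 by 1.68 ± 0.17. Cthrc1 rose by 1.28 ± 0.08, Fcrls by 1.26 ± 0.07, Adamtsl2 by 1.21 ± 0.06 and Serpina3n by 1.16 ± 0.09. Ephx2, the soluble epoxide hydrolase, rose by 1.23 ± 0.12, the growth factor gene Igf1 by 1.17 ± 0.09 and Wfdc17 by 1.17 ± 0.16. Sphkap fell by 1.87 ± 0.22, Mylk4 by 1.42 ± 0.06, Nox4 by 1.16 ± 0.06 and Acan by 1.16 ± 0.14. Htr1b fell by 1.03 ± 0.11, Gmnc by 1.08 ± 0.12, Lratd1 by 1.07 ± 0.05, Col15a1 by 1.00 ± 0.05, Pnldc1 by 0.99 ± 0.06 and Ppp1r36 by 0.99 ± 0.06. The 2 groups of arrays were fully apart within each genotype for all 20 genes, as the naming rule requires. Limma's adjusted p was at most 0.000188, while Tgfbr2 stood at -0.02 ± 0.04. With the immediate early score as a covariate, chosen after the data were seen, 2003 genes changed, 946 upward and 1057 downward.

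The knockout effects of the 2 genotypes correlated across the 14944 genes with a Pearson r of 0.62 and a Spearman rho of 0.55, genes not being independent replicates. The 2 effects share no array. Of the genes called in each genotype, 457 rose in both, where 105 would be shared by independent calls, and 457 fell in both, where 83.4 would be. Opposite calls numbered 10 genes that rose in the wild-type and fell in the mutant and 5 the other way. Among the genes changed in the wild-type, the slope of the mutant effect on the wild-type effect was 0.51. Choosing genes by their wild-type effect lowers this slope even where the 2 effects are equal, so it does not measure a weaker effect in the mutant.

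The mean effect moved 8 lists, each upward and none past the threshold with an estimated correlation. Fry's test, which asks whether a list's genes move one way on balance and does not compare them with other genes, put 18 of the 24 lists past the threshold here. It put 10 and 13 there for the knockout in the wild-type and the mutant, 5 and 10 for the mutation in controls and knockouts and 9 for the difference of effects. All 27 macrophage genes rose (27 adjusted over the list alone), with a median of 0.74 and a camera adjusted p of 1.85e-20, against adjusted p = 0.159 with an estimated correlation. Of 29 cell division genes 28 rose (28 adjusted over the list alone), with a median of 0.52 and an adjusted p of 3.11e-16, against adjusted p = 0.269 with an estimated correlation. Cytokines and chemokines had a median of 0.26 with 15 of 26 risen (18 risen and 1 fallen adjusted over the list alone; adjusted p 4.6e-06), against adjusted p = 0.089 with an estimated correlation. Interferon-induced genes had 13 of 23 risen (20 adjusted over the list alone), endothelial genes 15 of 24 risen and 1 fallen (17 and 1 adjusted over the list alone), and immediate early genes 12 of 30 risen (16 adjusted over the list alone). These 3 lists had a camera adjusted p of 6.48e-06, against adjusted p = 0.467 with an estimated correlation. Cardiac genes (adjusted p 0.000325) had 9 of 24 risen and 1 fallen (15 and 1 adjusted over the list alone), and ERK feedback genes (adjusted p 0.0124) had 8 of 20 risen and 1 fallen (9 and 1 adjusted over the list alone), both against adjusted p = 0.467 with an estimated correlation. The ERK feedback call ended without mutant knockout 1 (adjusted p 0.056), with the filter at the median (0.0521) and with the immediate early score as a covariate (0.92). Its adjusted p lay between 0.000788 and 0.92 over all alternatives. Median and mean, or median and test, had opposite signs in the TGF-beta target, collagen, proteoglycan and endoplasmic reticulum stress lists, none of which passed. Shuffling the knockout labels within each genotype moved up to 18 lists, so that the number of lists moved did not set this comparison apart.

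**Figure D2:**
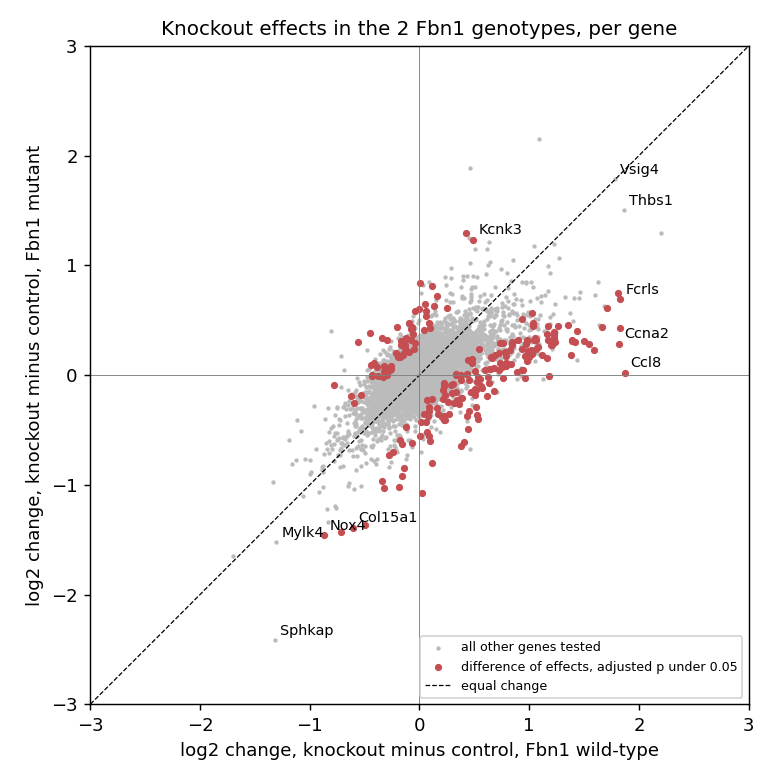
Knockout effects on 14944 genes, as the log2 difference between knockout and control in the Fbn1 wild-type (horizontal axis) and in the Fbn1 mutant (vertical axis). Each point is a gene, red points are the 221 genes whose effects differ, the dashed line marks equal change and labels give genes named in the text. Effects correlate with a Pearson r of 0.62, and the slope among genes changed in the wild-type, a choice of genes that lowers it, is 0.51.

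Among the controls, the Fbn1 mutant was compared with the wild-type. Clock genes, heat shock genes and Nnt differed between these groups. The mutation therefore cannot be told apart from collection time or other differences between them. Of the gene lists 5 passed, each upward, and 0 of them with an estimated correlation. Tnc rose by 1.49 ± 0.13, the matrix protease Adamts12 by 1.36 ± 0.10 and the carboxypeptidase Cpz by 1.30 ± 0.12. Ccna2 rose by 1.35 ± 0.18, the proliferation marker Mki67 by 1.14 ± 0.17 and Ccnb2 by 1.12 ± 0.14. P2rx1, an ATP-gated channel of smooth muscle, rose by 1.05 ± 0.13 and the secreted protein gene C1qtnf6 by 1.04 ± 0.06. The clock genes Ciart and Nr1d1, both transcriptional repressors, rose by 1.76 ± 0.35 and 1.11 ± 0.23, and Nfil3, a repressor of the opposite phase, fell by 1.25 ± 0.23. The potassium channel genes Kcnj15 and Kcnc4 fell by 1.27 ± 0.13 and 1.05 ± 0.08, Bmp3 by 1.24 ± 0.14, and Faim2, an inhibitor of apoptosis, by 1.32 ± 0.15. Hsph1, a heat shock protein, fell by 1.19 ± 0.11, Gpr165 by 1.18 ± 0.15, Gmnc by 1.08 ± 0.16 and Ccdc85a by 1.05 ± 0.10. Nnt, the mitochondrial transhydrogenase, fell by 1.07 ± 0.24. The 20 genes had fully separated groups, as the naming rule requires, and a limma adjusted p of at most 0.021, and Tgfbr2 stood at 0.04 ± 0.05. In all, 970 genes changed, 473 upward and 497 downward, and of these 12 rose and 13 fell at least 2-fold. The direction of this small excess turned without wild-type control 1 (392 up and 323 down) and with every probe set tested by itself (463 and 432). The count was 479 without wild-type control 2, 554 without wild-type control 3, 532 without mutant control 1 and 349 without mutant control 2. Ciart lost its call without mutant control 2 (adjusted p 0.0544), Nr1d1 without wild-type control 1, mutant control 1 or mutant control 2 (up to 0.0782) and Nnt without wild-type control 2, mutant control 1 or mutant control 2 (up to 0.0796).

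The collagen and cell division lists moved furthest in the mutant controls. Of 29 collagen genes 15 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 0.29 and a camera adjusted p of 2.85e-11, against adjusted p = 0.137 with an estimated correlation. The fibrillar collagens Col1a1 and Col3a1 rose by 0.68 ± 0.07 and 0.56 ± 0.08, and Col4a5 by 0.46 ± 0.05. Of 29 cell division genes 16 rose (21 adjusted over the list alone), with a median of 0.43 and an adjusted p of 1.27e-17, against adjusted p = 0.218 with an estimated correlation. Proteases and inhibitors had a median of 0.09 with 3 of 28 risen and 1 fallen (6 and 2 adjusted over the list alone; adjusted p 0.0179), against adjusted p = 0.137 with an estimated correlation, and Ctsk rose by 0.63 ± 0.05. Macrophage genes had a median of 0.17 with 3 of 27 risen (5 adjusted over the list alone; adjusted p 1.57e-05) and lymphocyte genes a median of 0.23 with 1 of 10 risen (3 adjusted over the list alone; adjusted p 0.0159), both against adjusted p = 0.634 with an estimated correlation. The elastic fibre list did not pass (adjusted p 0.163), with 3 of 18 risen and 2 fallen (4 and 3 adjusted over the list alone), but Eln rose by 0.75 ± 0.10 and the microfibril gene Mfap2 by 0.66 ± 0.11. The TGF-beta target, cytokine, interferon, fibroblast and immediate early lists had a median that differed in sign from the mean or the test and did not pass. Without mutant control 3 the count of lists was 3, as the macrophage (adjusted p 0.0758) and lymphocyte (0.212) calls ended. Their medians were then 0.07 and 0.04. The lymphocyte call also ended without wild-type control 2 (0.0899) and the protease call without wild-type control 1 (0.0685) or mutant control 1 (0.0639), and other splits of the 6 arrays gave up to 11 lists. Without the 2 arrays of highest Ucp1 the macrophage (0.0608) and lymphocyte (0.217) calls ended, and the lymphocyte call did with no filter (0.124). Their adjusted p lay between 1.15e-08 and 0.634 and between 0.000104 and 0.634 over all alternatives.

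Among the knockouts, the Fbn1 mutant was compared with the wild-type in the same way. Clock and heat shock genes differed between these groups too, with the clock arms 0.82 apart and 12 of 17 heat shock genes lower. Here as well the mutation cannot be told apart from collection time or other differences between the groups. Ccl8 fell by 1.69 ± 0.15 and Ifi205, an interferon-induced gene, by 2.00 ± 0.26. Glp1r, the receptor of glucagon-like peptide 1, fell by 1.72 ± 0.12 and the homeobox gene Meox1 by 1.65 ± 0.06. The collagen gene Col8a1 fell by 1.56 ± 0.20 and Thbs4, a matricellular protein, by 1.19 ± 0.21. Idi1, an enzyme of isoprenoid synthesis, fell by 1.23 ± 0.15, Ttc9 by 1.38 ± 0.20, Kcnj15 by 1.28 ± 0.13 and Sphkap by 1.17 ± 0.31. On the other side, Timp4 rose by 1.29 ± 0.15, P2rx1 by 1.25 ± 0.13, Kcnk3 by 1.15 ± 0.11 and Cpz by 0.97 ± 0.12. Ciart, Nr1d1 and Dbp, genes of the circadian clock, rose by 1.42 ± 0.35, 1.20 ± 0.23 and 0.99 ± 0.13. Tcap, a sarcomere protein of striated muscle, rose by 1.40 ± 0.25, Rasd2 by 1.04 ± 0.10 and Olfml2a by 0.94 ± 0.10. The 20 genes had fully separated groups, as the naming rule requires, and a limma adjusted p of at most 0.0428. Tgfbr2 stood at 0.16 ± 0.05 with an adjusted p of 0.0943. In all, 890 genes changed, 418 upward and 472 downward, and of these 7 rose and 17 fell at least 2-fold. The excess turned with the filter at the median (467 up and 454 down), without wild-type knockout 2 (305 and 296) and without mutant knockout 2 (314 and 285). The count was 457 without wild-type knockout 1, 498 without wild-type knockout 3 and 382 without mutant knockout 1, and 409 without the 2 arrays of highest Ucp1, an alternative chosen after the data were seen. Ciart lost its call without wild-type knockout 2 or 3 or mutant knockout 1 or 2 (adjusted p up to 0.124), Nr1d1 without mutant knockout 1 (0.0521), and Sphkap without any 1 of 8 arrays, among them all of its 6 except wild-type knockout 3 (up to 0.14).

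In the mutant knockouts 13 lists were lower than in the wild-type knockouts and 2 higher, and 2 of the 15 passed with an estimated correlation. Of 27 macrophage genes 13 fell (20 adjusted over the list alone), with a median of -0.43 and a camera adjusted p of 7.82e-17, against adjusted p = 0.116 with an estimated correlation, and Fcgr2b fell by 0.73 ± 0.06. The endoplasmic reticulum stress list had a median of -0.16 with 7 of 25 fallen (12 adjusted over the list alone; adjusted p 6.85e-08), and the chaperone Hspa5 and its partner Sdf2l1 fell by 0.52 ± 0.07 and 0.75 ± 0.10. TGF-beta targets had a median of -0.17 with 7 of 28 fallen (9 fallen and 1 risen adjusted over the list alone; adjusted p 6.61e-06), Nox4 at -0.86 ± 0.09 and Ltbp2 at -0.74 ± 0.11. Of the 15 lists past the threshold these last 2 were the ones to hold, at adjusted p = 0.0392 and 0.0378 with an estimated correlation. Proteoglycans fell with a median of -0.13 and 5 of 27 fallen and 1 risen (10 and 4 adjusted over the list alone; adjusted p 0.00233), Vcan, the proteoglycan versican, at -0.65 ± 0.08, and cytokines and chemokines with a median of -0.09 and 6 of 26 fallen and 1 risen (9 and 2 adjusted over the list alone; adjusted p 0.00558), both against adjusted p = 0.121 with an estimated correlation. Collagens had a median of -0.03 with 5 of 29 fallen (7 adjusted over the list alone; adjusted p 0.00898), elastic fibre genes a median of -0.10 with 5 of 18 fallen (7 adjusted over the list alone; adjusted p 0.00174), and proteases a median of -0.06 with 6 of 28 fallen and 1 risen (11 and 3 adjusted over the list alone; adjusted p 0.0108). In the order of these 3 lists, the values were adjusted p = 0.367, 0.269 and 0.111 with an estimated correlation. Fibroblast genes had a median of -0.13 with 1 of 24 fallen (7 adjusted over the list alone; adjusted p 0.00233), and the TGF-beta pathway list a median of -0.08 with 3 of 24 fallen (4 adjusted over the list alone; adjusted p 0.00757). Cartilage and bone genes had a median of -0.07 with 3 of 27 fallen and 1 risen (3 and 1 adjusted over the list alone; adjusted p 0.0199), the cartilage transcription factor Sox9 at -0.62 ± 0.08, and nerve genes a median of -0.08 with 2 of 13 fallen (2 adjusted over the list alone; adjusted p 0.0292). In the order of these 4 lists, the values were adjusted p = 0.349, 0.116, 0.149 and 0.397 with an estimated correlation.

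Cell division genes passed downward in the mutant knockouts with a median of -0.08 although 0 of 29 members fell (0 adjusted over the list alone; adjusted p 0.0176), against adjusted p = 0.719 with an estimated correlation. Skeletal muscle genes passed upward with a median of 0.09 and 2 of 15 risen (3 adjusted over the list alone; adjusted p 0.00763), the sarcomere gene Myoz1 at 0.64 ± 0.10, and cardiac genes with a median of 0.11 and 2 of 24 risen and 1 fallen (2 and 1 adjusted over the list alone; adjusted p 0.00813), against adjusted p = 0.149 and 0.349 with an estimated correlation. The contractile, lymphocyte and ERK feedback lists, none past the threshold, had a median that differed in sign from the mean or the test. Without mutant knockout 3 the count of lists was 7, as the TGF-beta pathway, protease and cartilage (adjusted p 0.0692 each), elastic fibre (0.0987), collagen (0.1), fibroblast (0.0544), nerve (0.0715) and cell division (0.724, with the direction turned) calls ended. Single calls ended without wild-type knockout 3 for cell division (0.337), without wild-type knockout 2 for nerve (0.205, with a median of -0.012) and without mutant knockout 2 for cardiac genes (0.0854), and other splits of the 6 arrays gave up to 17 lists. The filter at the median ended the cell division (0.155), cardiac (0.268) and cartilage and bone (0.0961) calls, array weights the cell division (0.757) and nerve (0.0695) calls, and the immediate early score the collagen call (0.0565). Over all alternatives the adjusted p lay between 6.82e-08 and 0.757 for cell division, 0.000423 and 0.349 for cardiac, 0.00575 and 0.149 for cartilage and bone, 0.0122 and 0.397 for nerve and 0.00132 and 0.367 for collagen genes.

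The Fbn1 effects in controls and in knockouts correlated across genes with a Pearson r of 0.35 and a Spearman rho of 0.25, and they share no array. Of the called genes 93 rose in both settings, where 13.2 would be shared by independent calls, and 110 fell in both, where 15.7 would be. Another 15 rose in controls and fell in knockouts and 3 did the reverse. Differences other than the mutation that both settings share, such as collection time, could add to the shared calls.

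**Figure D3:**
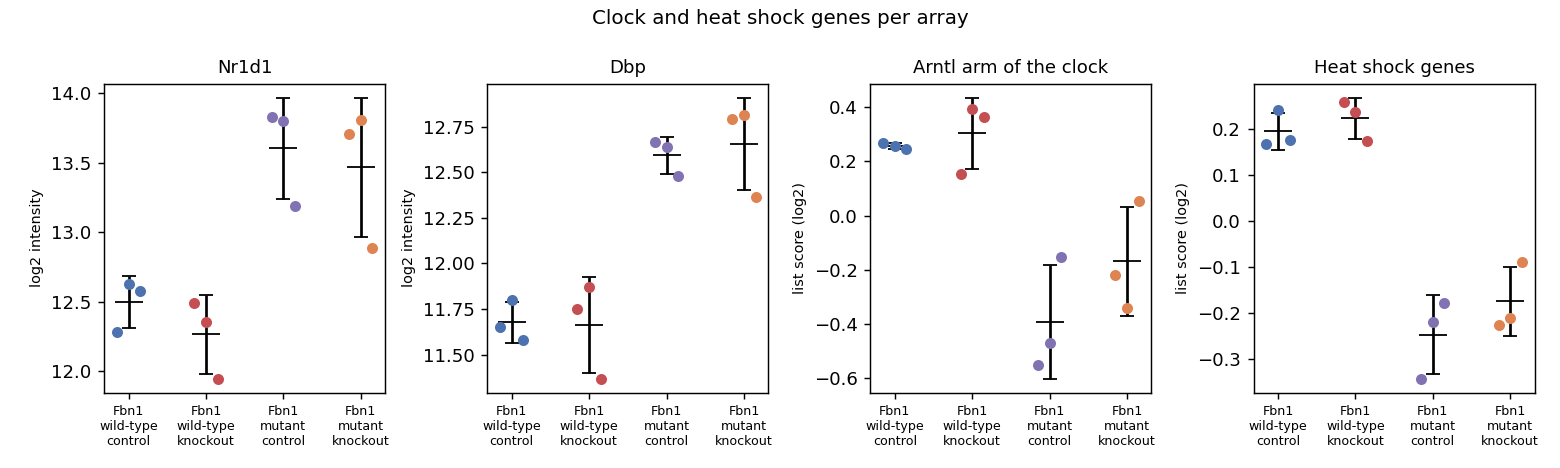
Log2 intensity of the clock genes Nr1d1 and Dbp and scores of the Arntl arm of the clock and of heat shock genes, as mean log2 values relative to the mean of all arrays (vertical axes), by group (horizontal axes). Points are arrays, horizontal lines group means of 3 arrays and bars 1 SD, and the scored genes were chosen after their values were seen. Heat shock scores lie between -0.34 and -0.09 in the 6 Fbn1 mutant arrays and between 0.17 and 0.26 in the 6 wild-type arrays.

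The last comparison tested whether the knockout effect itself differed between the Fbn1 genotypes, as the mutant effect minus the wild-type effect. For Ccl8 the difference was -1.85 ± 0.22, for Fcrls -1.14 ± 0.14 and for D17H6S56E-5 -1.40 ± 0.17. For Ccna2 and Ccnb2 it was -1.53 ± 0.26 and -1.36 ± 0.19 and for Mki67 -1.20 ± 0.23. Ccna2, Ccnb2 and Mki67 were also named as higher in mutant than in wild-type controls, and that higher level in the controls is part of their difference. For Timp1 the difference was -1.26 ± 0.18, for Glp1r -1.22 ± 0.16, for Meox1 -1.19 ± 0.09 and for Sfrp4, a secreted regulator of Wnt signalling, -1.19 ± 0.25. Positive differences were smaller. For Slc2a4, the insulin-regulated glucose transporter, it was 0.84 ± 0.10, for Kcnc4 0.84 ± 0.11 and for Kcnk3 0.74 ± 0.15. For the glutathione transferase Gstm7 and the ubiquitin ligase subunit Asb2 it was 0.70 ± 0.10 each, for the growth factor gene Fgf1 0.68 ± 0.10 and for P2rx6, an ATP-gated channel, 0.64 ± 0.10. For Rasl10b it was 0.87 ± 0.18, for the small RNA Scarna17 0.86 ± 0.19 and for Rbm24, an RNA-binding protein of muscle, 0.63 ± 0.13. Limma's adjusted p of the 20 genes was at most 0.0467, and Tgfbr2 stood at 0.12 ± 0.07. In all, 221 genes differed, 60 upward and 161 downward, and 20 of them by at least 2-fold, each downward. The largest class, 88 genes, rose in the wild-type and was not called in the mutant, 31 rose in both, 31 were called, upward, in the mutant and not in the wild-type, and 10 rose in the wild-type and fell in the mutant. The count was 107 without wild-type knockout 1, 109 without wild-type knockout 3, 118 without mutant control 2, 142 without mutant knockout 1 and 128 without mutant knockout 2, and 132 with the immediate early score as a covariate, chosen after the data were seen. Without wild-type knockout 1 or wild-type knockout 3, and without 4 to 7 other arrays each, Rasl10b (adjusted p up to 0.102), Scarna17 (0.107), Kcnk3 (0.0835), Rbm24 (0.0917), Mki67 (0.0764) and Sfrp4 (0.096) lost their calls.

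Of the 12 lists whose knockout effect differed, 11 did so downward in the mutant, and 3 of the 12 passed with an estimated correlation. Collagens had a median difference of -0.28 with 7 of 29 lower (17 adjusted over the list alone; camera adjusted p 1.69e-16), and Col4a5 stood at -0.76 ± 0.07, Col15a1 at -0.79 ± 0.10 and Col5a2 at -0.60 ± 0.09. TGF-beta targets had a median of -0.18 with 3 of 28 lower (8 adjusted over the list alone; adjusted p 2.2e-07), Col1a1 at -0.57 ± 0.10, and proteases a median of -0.09 with 5 of 28 lower (7 lower and 1 higher adjusted over the list alone; adjusted p 0.000117), Ctsk at -0.81 ± 0.07 and Ctss at -0.90 ± 0.13. These 3 lists held, at adjusted p = 0.0256, 0.019 and 0.0192 with an estimated correlation. Their calls are not fully separate, as 4 of 29 collagen genes and 9 of 28 TGF-beta targets also stand in another list, and Col1a1 in both of these. Macrophage genes had a median of -0.59 with 10 of 27 lower (21 adjusted over the list alone; adjusted p 3.25e-23), cell division genes a median of -0.54 with 7 of 29 lower (20 adjusted over the list alone; adjusted p 5.71e-20) and proteoglycans a median of -0.14 with 3 of 27 lower (3 adjusted over the list alone; adjusted p 4.04e-05), against adjusted p = 0.0574, 0.0737 and 0.0574 with an estimated correlation. Elastic fibre genes had a median of -0.23 with 1 of 18 lower (8 adjusted over the list alone; adjusted p 2.77e-05), Eln at -0.94 ± 0.14, and cytokines and chemokines a median of -0.14 with 2 of 26 lower (3 adjusted over the list alone; adjusted p 0.000578), Ccl2 at -0.80 ± 0.12, against adjusted p = 0.156 and 0.0666 with an estimated correlation. Fibroblast genes had a median of -0.11 with 3 of 24 lower (4 adjusted over the list alone; adjusted p 0.00117), lymphocyte genes a median of -0.27 with 0 of 10 lower (1 adjusted over the list alone; adjusted p 0.0262) and endoplasmic reticulum stress genes a median of -0.09 with 0 of 25 lower (0 adjusted over the list alone; adjusted p 0.00772). Skeletal muscle genes were the 1 list to differ upward, with a median of 0.14 and 0 of 15 higher (1 adjusted over the list alone; adjusted p 0.00772). In the order of these 4 lists, the values were adjusted p = 0.358, 0.495, 0.17 and 0.156 with an estimated correlation. The ERK feedback and the cartilage and bone lists had a median and a test of opposite sign and did not pass. The lymphocyte call ended without wild-type control 2 (adjusted p 0.12), wild-type knockout 2 (0.0654), mutant control 3 (0.216) or mutant knockout 3 (0.0586), and the endoplasmic reticulum stress call without mutant knockout 3 (0.137). The lymphocyte call also ended with no filter (0.132), with array weights (0.0511) and without the 2 arrays of highest Ucp1 (0.247), and its median was -0.08 without mutant control 3 and with no filter. Its adjusted p lay between 0.000939 and 0.495 over all alternatives. The endoplasmic reticulum stress call ended with the immediate early score (0.0508), between 0.000348 and 0.17 over all. The skeletal muscle call ended with no filter (adjusted p 0.0949, median 0.09) and with the filter at the median (0.0565, median 0.23). Its adjusted p lay between 0.00173 and 0.156 over all alternatives. The mean cell division score was -0.51 in wild-type controls and 0.31 in wild-type knockouts, and -0.02 and 0.22 in the mutant. For collagen the scores were -0.11 and 0.06, and 0.11 and -0.06. Both lists were thus higher in mutant than in wild-type controls, and this is part of their difference of effects. Shuffled residuals of a fit without the difference gave up to 18 lists.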

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

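Of the tests in this part, both tests of the Tgfbr2 level, the test of the macrophage pattern without mutant control 3 and both clock tests without Nfil3 were chosen only after the result was seen.

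The knockout effect differed between the Fbn1 genotypes for 221 genes by the test of the difference itself. Of 100 shufflings of the residuals of a fit without the difference, the real one included, 1 gave as many genes, and the highest of the others gave 4. This makes chance unlikely for the count only if the arrays are separate animals. Shuffled residuals also hold the difference itself as spread, which lowers the other counts. The count was 107 without wild-type knockout 1, 109 without wild-type knockout 3, 118 without mutant control 2, 142 without mutant knockout 1 and 128 without mutant knockout 2. By the same test 12 lists differed, of which 3 (TGF-beta target, collagen and protease) passed with an estimated correlation and 9 did not. Their median differences were -0.59 for macrophage, -0.54 for cell division, -0.28 for collagen, -0.27 for lymphocyte, -0.23 for elastic fibre, -0.18 for TGF-beta target, -0.14 for proteoglycan, -0.14 for cytokine and chemokine, -0.11 for fibroblast, -0.0851 for protease, -0.0907 for endoplasmic reticulum stress and 0.14 for skeletal muscle genes. The lymphocyte median was -0.08 without mutant control 3 (adjusted p 0.216) and also -0.08 with no filter on dim probe sets (0.132), and the adjusted p lay between 0.000939 and 0.495 over all alternatives. The endoplasmic reticulum stress call ended without mutant knockout 3 (0.137) and the skeletal muscle call with no filter (0.0949) or the filter at the median (0.0565), with ranges of 0.000348 to 0.17 and 0.00173 to 0.156. As many lists as these 12 came from 21 of the 100 shufflings, the highest of the others giving 18, so chance is not excluded for the number of lists.

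Among the named genes, the difference of the effects was negative for Ccl8 (-1.85), Ccna2 (-1.53), D17H6S56E-5 (-1.40), Ccnb2 (-1.36), Timp1 (-1.26), Glp1r (-1.22), Mki67 (-1.20), Sfrp4 (-1.19), Meox1 (-1.19) and Fcrls (-1.14). It was also negative for Serpina3n (-1.10), Igfbp2 (-1.10), Cthrc1 (-1.06), Tnc (-1.02), C1qtnf6 (-1.01), Adamts12 (-0.94), Col15a1 (-0.79), Lratd1 (-0.72) and Nox4 (-0.59). It was positive for Rasl10b (0.87), Scarna17 (0.86), Slc2a4 (0.84), Kcnc4 (0.84), Kcnk3 (0.74), Gstm7 (0.70), Asb2 (0.70), Fgf1 (0.68), P2rx6 (0.64) and Rbm24 (0.63). Ccna2, Ccnb2, Mki67, Tnc, C1qtnf6 and Adamts12 were named as higher, and Kcnc4 as lower, in mutant than in wild-type controls, and this is part of their difference. Nox4 lost its call without any 1 of the arrays except mutant knockout 3 (adjusted p up to 0.093). Rasl10b, Scarna17, Kcnk3, Rbm24, Mki67 and Sfrp4 lost theirs without wild-type knockout 1 or wild-type knockout 3, and without 4 to 7 other arrays each (adjusted p up to 0.107).

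Probe sets without a single gene name, which the comparisons leave out, also changed. They numbered 566 for knockout against control in the wild-type, 326 in the mutant and 1061 for the mean of both genotypes. For the Fbn1 mutation they numbered 199 among controls and 98 among knockouts, and 17 for the difference of the knockout effects. In every comparison they changed less often than probe sets with 1 symbol. For the knockout in the wild-type 478 of 6464 tested without a name (7.4%) and 88 of 975 with several symbols (9.0%) changed, against 15.4% of those with 1 symbol. For the difference the shares were 0.26% and 0% against 0.65%.

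The other counts were set against other groupings of the arrays. For the mean knockout effect 1 of 100 shufflings of the knockout labels, the real one, gave as many genes as the 4316 found. The highest of the others gave 673. Other labellings count part of the knockout effect as spread, which lowers their counts, so the size of this gap is no measure of chance. The share of 1 in 100 makes chance unlikely for that count only if the arrays are separate animals. As many as its 8 lists came from 61 of the 100, the highest of the others giving 18, so chance is not excluded there. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each of these 4 comparisons 1 of 10 splits, the real one, gave as many genes, with 2814, 2008, 970 and 890 genes against 0 in the highest of the others. For lists, as many came from 3 splits for the knockout in the wild-type (12 lists, highest other 14), from 2 in the mutant (15, highest other 15), from 7 for the mutation among controls (5, highest other 11) and from 4 among knockouts (15, highest other 17).

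The Tgfbr2 probe set showed no clear fall in arrays labelled knockout. Its difference was -0.08 in the wild-type, between -0.12 and -0.04 over all alternatives, and 0.04 in the mutant, neither past the threshold. The feedback genes Pmepa1, Ldlrad4, Skil and Smad7 had a median log2 difference of -0.47 (standard error 0.06 for their score), but they were chosen after their values were seen, and the score of the TGF-beta target list moved by 0.12 in the wild-type and by -0.10 in the mutant (standard error 0.03 each). An exchange of the knockout and control labels therefore stays open. Probes that lie outside the deleted part could leave the level as it was, and the difference of -0.0184 with a standard error of 0.0368 has the size this needs, but it rests on 1 probe set without values per probe, so this stays open. Incomplete recombination, or receptor transcripts of cells in which the Cre does not act, stay open too and were not tested.

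Macrophage genes were higher in the knockouts, and less so in the Fbn1 mutant, by 0.94 and 0.39 on the score of 27 genes, of which C1qb, Lyz2 and Lyve1 are the most abundant at 11.95, 11.75 and 11.70 and 0 stand in another list. The list passed at the preset correlation but not otherwise, at adjusted p = 0.0651 in the wild-type, 0.305 in the mutant and 0.0574 for the difference with an estimated correlation. With the fibroblast and adipocyte scores as covariates the wild-type difference was 0.83 (standard error 0.09), against 0.94 before. These 2 scores, as measured, therefore did not account for most of it. They are rough measures of fat and adventitia, and the fibroblast score itself was 0.10 in wild-type knockouts and -0.04 in wild-type controls. More fat or adventitia in the knockout samples is thus not excluded. The same covariates left the difference between the genotypes at -0.53 (standard error 0.11), against -0.55 before, and leaving out mutant control 3, the highest macrophage score among the mutant controls, left it at -0.45 (standard error 0.09). A biological effect of the knockout was not tested and stays open, and it cannot be separated from an effect of tamoxifen in this design.

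Clock genes differed between the Fbn1 genotypes in controls and in knockouts. Over 6 members of the Dbp arm and 4 of the Arntl arm, among them Nfil3, one of the largest decreases in the controls, the arms moved apart by 0.87 in controls and 0.82 in knockouts (standard error 0.15 each), and without Nfil3 by 0.67 and 0.78 (standard error 0.16 each). This is what a different time of day of collection would give, so collection time is a candidate explanation of this pattern. Mutant control 3 did not carry the pattern. Its scores of the full Dbp and Arntl arms, 0.23 and -0.15, lay nearest the wild-type among the mutant controls. Leaving it out therefore widened the gap in the controls, to 0.97 (standard error 0.16) and, without Nfil3 too, to 0.73 (standard error 0.19). This leave-out could not have shrunk the gap and says nothing on other single arrays. An effect of the Fbn1 mutation on the clock stays open, as the labels give no collection times.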

How the results depend on the processing

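Leaving out the 2 arrays of highest Ucp1 (mutant control 3 and mutant knockout 1) and the 2 score covariates were chosen only after the data were seen, and the other alternatives were planned. Over these, 504 results of named genes gave 12393 values, of which 11346 kept their direction and side of the threshold, 1044 lost the call, 1 gained one and 2 changed sign, and 336 results kept both in every alternative run for them. Of 67 results of lists past the threshold 6 did so, with 1493 of 1651 values unchanged in call, 154 calls lost and 4 reversed. All 12 counts of genes and lists stayed within 1.5 times their value under both filters, both rescalings, the mean of a gene's probe sets, the trended variance model and the number in the titles as a block. That block does not appear to pair the arrays, as same-number arrays of different groups correlated between -0.22 and 0.24 after group means were removed.

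Array weights raised the genes changed to 3687 for the knockout in the mutant, 1568 and 1687 for the mutation in controls and in knockouts, and 469 for the difference of effects. Fitting only the groups of the comparison, which leaves fewer arrays to estimate the spread, gave 1261 for the knockout in the mutant and 480 for the mutation in controls, and testing every probe set gave 123 for the difference. Without the 2 arrays of highest Ucp1 the knockout in the mutant changed 1082 genes and the mutation in knockouts 409, and the mutation in controls moved 3 lists. The adipocyte score as a covariate gave 1255 genes for the knockout in the mutant. The immediate early score gave 398 genes and 9 lists for the knockout in the mutant, 2003 genes for the mean effect and 132 for the difference. Camera with an estimated correlation left 1, 0, 0, 0, 2 and 3 lists in the order of the comparisons. The correlation of the knockout effects was 0.59 with no filter, 0.65 with the filter at the median, 0.59 without the 2 arrays of highest Ucp1 and 0.66 with the immediate early score. Except where stated, the cause was not tested. Fitting only the groups of a comparison gives no value for the mean effect or the difference, and testing every probe set gives none for lists.

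Leaving out 1 array at a time, the genes changed ranged from 1836 to 2992 for the knockout in the wild-type, from 896 to 2146 in the mutant, from 349 to 1073 for the mutation in controls, from 382 to 1019 in knockouts and from 107 to 202 for the difference of effects. For the mean effect the range was 3424 to 4330. The counts that moved by over 1.5 times were, for the knockout in the wild-type, 1836 and 1874 without wild-type knockouts 3 and 1, and in the mutant 1209 and 896 without mutant controls 1 and 2 and 1160 and 1049 without mutant knockouts 1 and 2. For the mutation in controls they were 479 and 554 without wild-type controls 2 and 3 and 532 and 349 without mutant controls 1 and 2, and in knockouts 457 and 498 without wild-type knockouts 1 and 3 and 382 without mutant knockout 1. For the difference they were 107 and 109 without wild-type knockouts 1 and 3, 118 without mutant control 2 and 142 and 128 without mutant knockouts 1 and 2. Lists ranged from 3 (without mutant control 3) to 6 for the mutation in controls and from 7 (without mutant knockout 3) to 18 in knockouts, and the correlation of effects from 0.58 to 0.64. With 1 array fewer a group of 2 remains, so lower counts also follow from fewer arrays.

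In all, 6 values changed direction. Tgfbr2 in the mean effect, never past the threshold, stood at 0.00843 with the adipocyte score and at 0.00214 without wild-type knockout 3, and its values without 1 array ranged from -0.0383 to 0.00214. With the immediate early score as a covariate, which by construction removes that list's own mean, the immediate early list had a median of -0.0583 in the mutant and -0.0115 in the mean effect, and the ERK feedback list tested downward in the mutant with a median of 0.0251. The cell division list among knockouts tested upward without mutant knockout 3, with a median of -0.0103 and an adjusted p of 0.724, and its medians without 1 array ranged from -0.178 to -0.0103 (adjusted p over its alternatives 6.82e-08 to 0.757). What the signal over background limits was not analysed here, beyond the 2 other filters on dim probe sets.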

Other observations

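The clock and heat shock lists below were chosen only after the data were seen, as were Ucp1, Adipoq and the test of the neighbours of Fbn1.

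Heat shock genes were lower in the Fbn1 mutant arrays of both settings. Of 17 members 12 fell among controls and 12 among knockouts, with medians of -0.40 and -0.37, and the knockout comparisons gave medians of 0.02 and 0.05. Hsph1, a co-chaperone of Hsp70, stood at -1.19 ± 0.11 and -1.12 ± 0.11, its relative Hspa4l at -0.79 ± 0.11 and -0.71 ± 0.11, and the chaperone Hsp90aa1 at -0.50 ± 0.07 and -0.37 ± 0.07. The call of Hsp90aa1 among knockouts ended without mutant knockout 1 (adjusted p 0.0504). In the Dbp arm of the clock 6 of 10 genes rose in controls and 8 in knockouts, with medians of 0.45 and 0.48. In the Arntl arm 2 of 4 fell in each, with medians of -0.52 and -0.46, and the core clock gene Clock stood at -0.40 ± 0.06 and -0.32 ± 0.06.

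Receptors and enzymes of vasoactive agents did not pass as a list in any comparison, yet single members moved. In the wild-type 8 of 22 rose with the knockout and 2 fell (10 and 5 adjusted over the list alone), among them the natriuretic peptide receptor Npr3 at 0.80 ± 0.07, the adrenergic receptor Adra1b at 0.65 ± 0.07 and P2rx1 at 0.85 ± 0.13, while Npr1 fell by 0.44 ± 0.07. In the mutant 3 rose and 3 fell (3 and 3 adjusted over the list alone), Adra1b at 0.73 ± 0.07 and P2rx1 at 1.05 ± 0.13. Agtr1a, the angiotensin II type 1 receptor, was higher in the Fbn1 mutant by 0.75 ± 0.08 among controls and by 0.53 ± 0.08 among knockouts, and Rgs4, a regulator of G protein signalling, was lower by 0.71 ± 0.13 and by 0.88 ± 0.13. Of the cartilage and bone genes, Sox9 rose with the knockout by 0.46 ± 0.08 in the wild-type and 0.38 ± 0.08 in the mutant.

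Fat markers varied between arrays of 1 group. Ucp1 ranged from 6.75 to 8.58, with 8.58 in mutant control 3 and 8.21 in mutant knockout 1, and the adipocyte hormone gene Adipoq ranged from 7.05 to 8.66. Adipocyte genes did not pass as a list in any comparison, and Pparg, a regulator of fat cells, rose with the knockout by 0.69 ± 0.12 in the wild-type and 0.60 ± 0.12 in the mutant.

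Nnt fell into 2 levels, which followed the Fbn1 genotype in the controls but not in the knockouts. Its decrease among the controls therefore cannot be assigned to the mutation. Nnt was 11.29, 11.72 and 11.21 in the wild-type controls, 11.10 in wild-type knockout 1 and 11.32 in mutant knockout 1, and between 10.30 and 10.48 in the other 7 arrays. Group means were 11.41 in controls and 10.60 in knockouts of the wild-type, and 10.34 and 10.74 in the mutant. The 2 levels were thus unevenly spread over the knockout comparisons and the difference of effects as well, and the cause was not tested. Xist lay between 6.29 and 6.67 and the Y-linked gene Eif2s3y between 10.75 and 11.05 on all 12 arrays. Of the 100 tested genes nearest to Fbn1 on its chromosome 2 were among the 203 genes that differed the same way between the Fbn1 genotypes in controls and knockouts, 2% against 1.35% of other genes, with a one-sided Fisher's exact p of 0.395. The erythroid list had 5 measured members of 18, of which 0 changed in the wild-type knockout comparison (0 adjusted over the list alone).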
